A study of Mus musculus with 4 samples.

How the data were processed

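The series holds single-cell RNA sequencing of cells from MC38 liver metastatic tumours, enriched for CD45 on beads, in 4 libraries, 1 for each combination of diet and tumour line. Groups were taken from the sample titles. For LFD_shYap the title and the treatment field disagree on diet, and the treatment field was run as an alternative. The deposited matrices hold raw UMI counts per gene and barcode, with no normalization, made with Cell Ranger 6.0.0 per the file headers. The submitters' processing notes name Cell Ranger 4.0.0, STAR 2.5.1 and the build mm10, so the version is given inconsistently in the sources used here. The chemistry was 10x Genomics 3′ v3.1, per the labels' protocols. The rule by which barcodes were kept before deposit is not given in the sources used here. Each matrix had 32285 genes, of which 32158 identifiers were matched to the GENCODE annotation of GRCm38 for coordinates. Because a 3′ count carries no information on the rest of a transcript, splice forms were not analysed here.

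From the deposited counts, barcodes with at least 200 detected genes and under 15% mitochondrial UMIs were kept. Mitochondrial filtering applied to 2209, 1876, 1649 and 1696 barcodes of LFD_WT, LFD_shYap, HFD_WT and HFD_shYap, and 0, 3, 0 and 11 barcodes had fewer than 200 genes. Doublets were scored per library against simulated doublets, with an expected rate of 0.8% per 1000 barcodes. The automatic threshold called 0 doublets in every library, which was read as a failure, so barcodes were ranked by their score and about the expected number removed, a choice made after the data were examined. This took 1681, 1034, 1439 and 716 barcodes, or 11.4%, 8.74%, 10.4% and 7.47%. In all 37910 of 50062 barcodes were kept. They were clustered together over 4 libraries with scanpy 1.11.5 on 2000 variable genes, 30 principal components and 15 neighbours, with Leiden resolution 1, giving 27 clusters, and the T lineage was clustered again into 12 sub-clusters. Clusters were named only by markers fixed before the data were examined, and those led by genes of another type, with too few markers or with low depth stayed unnamed. No batch correction was applied, since library and group cannot be separated with 1 library per combination.

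UMI counts were summed per library and lineage, for the 3 lineages with most cells: mononuclear phagocytes, T lineage and neutrophils. These sums held 63488417 to 77923148 UMIs per library for phagocytes, 3095765 to 6269021 for the T lineage and 722872 to 2084786 for neutrophils, so the neutrophil values are the least precise of these 3. Diet over both tumour lines and tumour line over both diets were tested on these counts with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr, an additive model of diet and line, and Benjamini-Hochberg adjustment at 0.05. This leaves 1 residual degree of freedom and counts any interaction of diet and line as error. The SE given with a log2 fold change is approximate, being its absolute value divided by the square root of the F statistic. Nothing in the labels says how many mice gave each library, so these p-values measure only the spread between these samples. The labels fixed which comparisons were made, and the tests, alternatives, 25 gene lists and the rule for named genes were set before the data were examined. Lists were tested with camera (limma 3.58.1), with its preset correlation of 0.01 and with an estimated correlation. No list call at the preset correlation held with an estimated one, in any of the 3 lineages or for either factor. With 1 residual degree of freedom an estimated correlation left little room for any call, the smallest unadjusted camera p being 0.057. Its values therefore do not test the preset calls. With the correlation fixed, a preset camera p-value compares the listed genes with the other genes. It does not measure the spread between libraries, so a very small value does not stand for replication.

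Between single libraries no test was made. CPM (UMI counts scaled to a common total) were compared with exact 95% Poisson intervals and shares with exact Clopper-Pearson intervals. For log2 ratios, a count under 3 was set to a floor of 3 counts per library. For each list, members with at least 20 UMIs over both libraries gave a median log2 ratio, ranked among 10000 random lists of the same size matched on mean expression. The all-gene median log2 ratio ran from -0.23 to 0.19 over the pairs and lineages, and list medians of pairs are given relative to it.

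The rule for named genes took Yap1, Ptprc and the sex-linked genes in every library. For the 3 main pairs and each lineage it took the 4 highest and 4 lowest CPM ratios among genes with at least 50 CPM and 30 UMIs in the higher library, with a count under 3 set to 3. Mitochondrial, ribosomal protein, immunoglobulin, T cell receptor variable, hemoglobin, Gm, Rik, clone-named and sex-linked genes were left out of that part. It also took up to 4 members per list with at least 100 UMIs and the largest absolute log2 ratio, and up to 10 genes per test and lineage with the smallest p-values past the threshold. A gene named outside this rule is said to have been chosen after its values were seen. Not every gene the rule took is named, and some are not reported here.

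Alternatives were DESeq2 1.42.0, RLE size factors, no expression filter, the tested factor alone, the diet of LFD_shYap from its treatment field, no doublet removal and each library left out in turn. With 3 libraries the tested factor stood alone in the model, and the lone library of an arm was assumed to vary like the others. For shares and ratios they were at least 500 genes, under 10% mitochondrial UMIs, Leiden resolution 0.5, cells thinned to 1000 UMIs, TMM-scaled CPM, CPM without the 20 most abundant genes, and list members with at least 100 UMIs. Some further alternatives were chosen after the data were seen: the low-depth cluster counted with the phagocytes, only cells with Xist or only cells with Y-linked UMIs from HFD_shYap, genes of another cell type left out, T and NK cells counted together, and T sub-cluster 1 left out. Also after the data were seen, the CPM of 10 macrophage markers in other lineages was expressed as a percentage of their CPM in phagocytes of the same library, and the median was taken.

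The edgeR step was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 64 and 88 of these for line and 58 and 91 for diet among 14179 genes in phagocytes, and 56 and 93 for line and 64 and 96 for diet among 10631 genes in the T lineage. In neutrophils, with 6505 genes, it recovered 14 and 78 for line, and 0 and 0 for diet. False calls among unchanged genes numbered 13 and 15 in phagocytes, 6 and 15 in the T lineage and 6 and 0 in neutrophils for line and diet. The list step put 6% of unchanged and 64% of lists shifted by 0.5 outside the central 95%. The simulated genes varied independently of each other, so 6% is not the rate for real lists whose members vary together. The random lists likewise do not keep such shared variation. NK and dendritic cells, outside the 3 lineages with most cells, were described only by values.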

Results

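Immune cells were profiled by droplet-based single-cell RNA sequencing (10x Genomics 3′ chemistry) from liver metastatic tumours formed in C57BL/6J mice by MC38, a mouse colon carcinoma line. Cells had been enriched on magnetic beads for CD45, the pan-leukocyte phosphatase encoded by Ptprc. There were 4 libraries, 1 for each combination of diet (low-fat, LFD, or high-fat, HFD) and tumour line (WT, or a Yap knockdown derivative labelled shYap), so no combination had a replicate. The question posed by the design is how diet and the knockdown in the tumour line alter the cells of the tumour. The labels of LFD_shYap conflict: its title gives the low-fat diet and its treatment field the high-fat diet. The title was used, and every diet value that includes this library depends on that reading. So do the tumour line tests adjusted for diet and the comparison of LFD_shYap with LFD_WT. Under the treatment field, that pair would differ in diet as well as tumour line. The deposited matrices held 14779 barcodes for LFD_WT, 11831 for LFD_shYap, 13870 for HFD_WT and 9582 for HFD_shYap, with 125854921, 127733073, 144936859 and 106268471 UMIs. After filtering, 10974, 8956, 10798 and 7182 cells were kept, with median depths of 6633.5, 8717, 8502 and 9786.5 UMIs per cell in the same order.

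Yap1 (ENSMUSG00000053110, GRCm38 chromosome 9, 7931999 to 8004596), the transcriptional co-activator targeted by the knockdown, stood at 4.20 CPM (UMIs scaled to a common total; exact 95% Poisson interval 3.799 to 4.63) over all kept cells of LFD_WT. It stood at 3.52 CPM (3.16 to 3.90) in LFD_shYap, 2.89 CPM (2.59 to 3.22) in HFD_WT and 1.66 CPM (1.40 to 1.96) in HFD_shYap. Clusters 1 and 14 were low in Ptprc; cluster 14 was fibroblast- or stellate-like by its markers, led by Col3a1, Dcn and Col6a1, and cluster 1 stayed unnamed. Their Y-linked RNA was at most 6.74% of the phagocyte level in LFD_WT, LFD_shYap and HFD_WT, which argues against stromal cells of the mice. Whether they are cells of the tumour line was not tested. Clusters 1 and 14 held 376 of 402, 327 of 355, 296 of 326 and 133 of 143 of these Yap1 UMIs in LFD_WT, LFD_shYap, HFD_WT and HFD_shYap. Within these clusters, Yap1 was at 21.01, 18, 16.9 and 21.9 CPM, from 738, 781, 694 and 145 cells. The ratio of the library labelled shYap to the WT library there was 0.857 (0.737 to 0.997) under low-fat diet and 1.30 (1.05 to 1.60) under high-fat diet. In cluster 14 alone the high-fat ratio was 1.22 (0.938 to 1.57) and in cluster 1 alone 1.39 (0.948 to 2.001). The low-fat ratio was 0.872 (0.717 to 1.063) in cluster 14 alone and 0.794 (0.616 to 1.018) in cluster 1 alone. Yap1 RNA of these clusters was therefore not lower in HFD_shYap than in HFD_WT, against its label. The knockdown libraries are therefore given as the libraries labelled HFD_shYap and LFD_shYap, the short forms HFD_shYap and LFD_shYap being names only, and every tumour line direction rests on these labels. Ptprc (ENSMUSG00000026395, chromosome 1, 138062861 to 138175708) was at 280, 275, 327 and 362 CPM over all kept cells and at 7.77, 7.54, 11.4 and 9.87 CPM in clusters 1 and 14. All Poisson and binomial intervals cover counting error only and not differences between mice.

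Sex-linked genes separated the library labelled HFD_shYap from the others. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), the RNA that silences a female X chromosome, had 30490 UMIs in this library (355 CPM), against 2 UMIs in LFD_WT, 3 in LFD_shYap and 8 in HFD_WT. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 110, 112 and 122 CPM in LFD_WT, LFD_shYap and HFD_WT, and were still at 101 CPM in the library labelled HFD_shYap. Of its 4162 phagocytes thinned to 5000 UMIs, 31.4% had Xist UMIs alone, 33.2% Y-linked UMIs alone and 2.6% both.

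**Figure D1:**
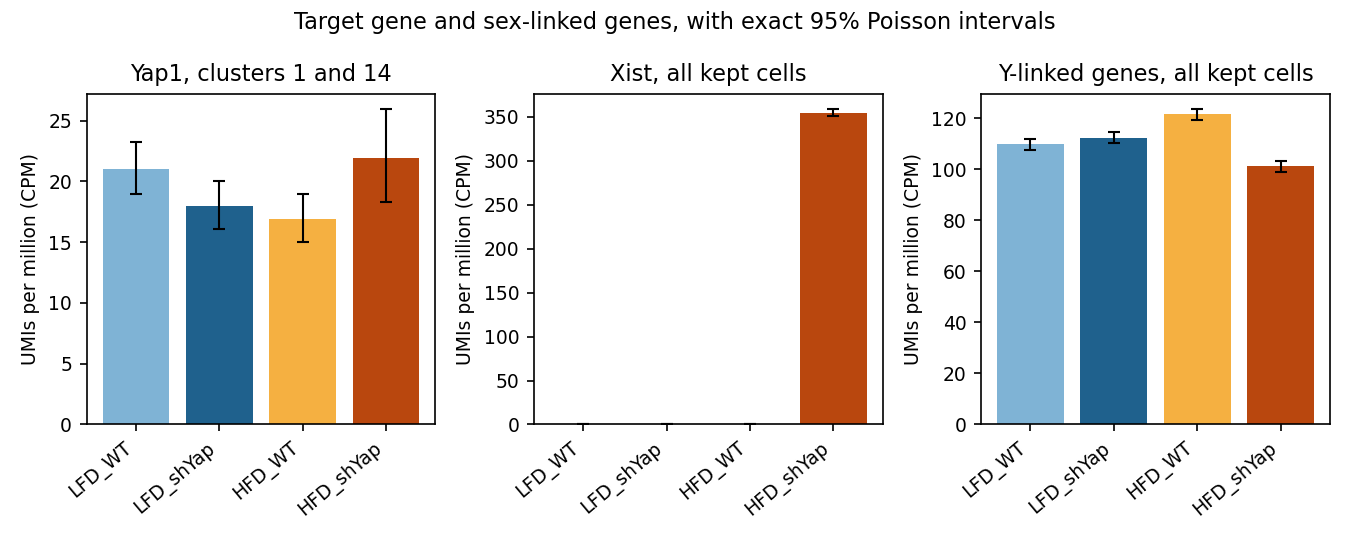
CPM of Yap1 in clusters 1 and 14, and of Xist and the summed Y-linked genes in all kept cells, for each of the 4 libraries; bars are library values and lines exact 95% Poisson intervals. Yap1 lay between 16.9 and 21.9 CPM, and Xist reached 355 CPM in the library labelled HFD_shYap alone.

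Mononuclear phagocytes, the macrophages and monocytes, made up 56.8% of the kept cells in LFD_WT, 64.7% in LFD_shYap, 57.2% in HFD_WT and 61.8% in HFD_shYap. The T lineage share was 5.64% (exact binomial interval 5.22 to 6.09) in LFD_WT, 7.24% (6.71 to 7.79) in LFD_shYap, 10.6% (10.0 to 11.2) in HFD_WT and 12.3% (11.6 to 13.1) in HFD_shYap. It was 4.94 percentage points (4.22 to 5.67) higher in HFD_WT than in LFD_WT, and T and NK cells together were 2.98 points (2.19 to 3.77) higher. After thinning to 1000 UMIs, 612 of 615 NK cells fell in the T class, which was then 2.39 points (1.56 to 3.22) higher. Between the libraries labelled shYap the diet difference was 5.10 points (4.18 to 6.04). Neutrophils were 3.64%, 3.89%, 8.82% and 6.49% of cells in the same library order, 5.18 points (4.54 to 5.82) higher in HFD_WT than in LFD_WT. NK cells were 2.72%, 1.82%, 0.759% and 0.989%, and dendritic cells 3.97%, 3.15%, 5.51% and 6.06%. Between tumour lines, the T lineage share was 1.75 points (0.802 to 2.72) higher in the library labelled HFD_shYap than in HFD_WT. It was 1.59 points (0.910 to 2.29) higher in LFD_shYap than in LFD_WT, against 0.690 points (-0.0951 to 1.48) for T and NK cells together and 0.119 points (-0.707 to 0.9497) for that joint class after thinning. The neutrophil share of the library labelled HFD_shYap differed from that of HFD_WT by -2.33 points (-3.10 to -1.54), or -3.30 points without doublet removal. LFD_shYap differed from LFD_WT in neutrophil share by 0.250 points (-0.279 to 0.787). The phagocyte share was 4.58 points (3.12 to 6.04) higher in the library labelled HFD_shYap than in HFD_WT and 7.92 points (6.56 to 9.27) higher in LFD_shYap than in LFD_WT, the latter becoming 0.632 points after thinning, when 1939 cells of a low-depth cluster joined the phagocytes. This unnamed cluster, with a median of 959 UMIs, held 17.5%, 8.78%, 8.52% and 8.65% of cells in LFD_WT, LFD_shYap, HFD_WT and HFD_shYap. Counted as phagocytes, it turned the low-fat line difference to -0.799 points and the HFD_WT difference from LFD_WT from 0.407 (-0.908 to 1.72) to -8.57 points, and thinning moved the latter to -7.21 points. Bead selection and the depth gap between libraries can set these shares.

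**Figure D2:**
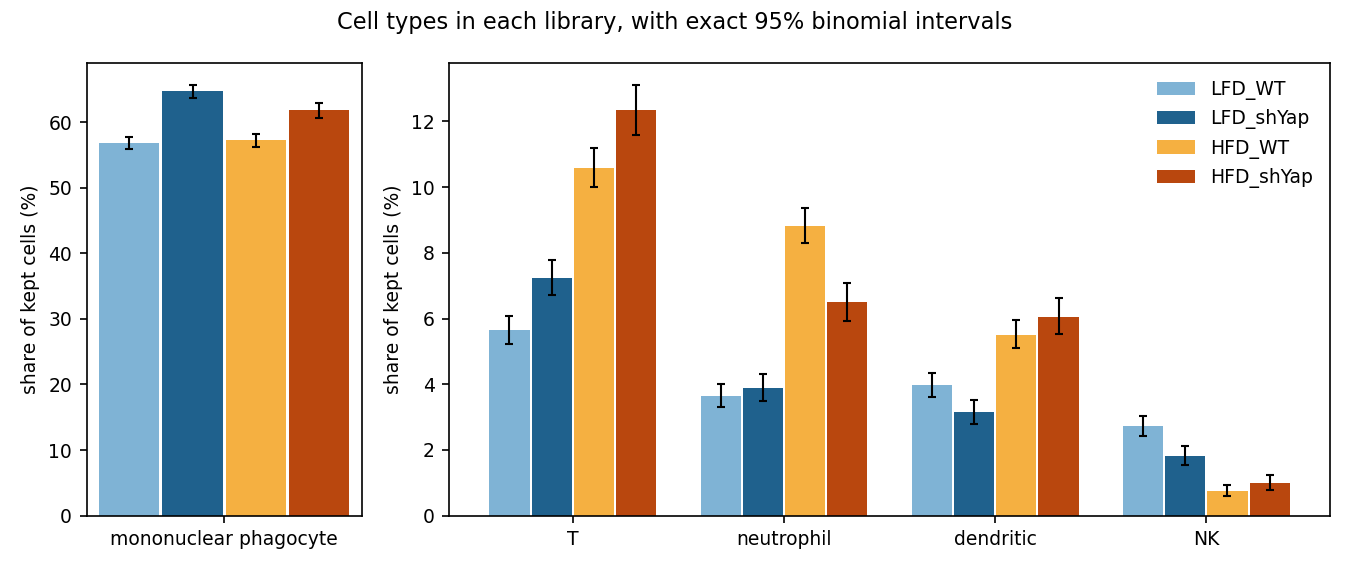
Shares of kept cells (percent) by cell type in each of the 4 libraries, with bars for library values and lines for exact 95% binomial intervals. The T lineage share ran from 5.64% in LFD_WT to 12.3% in the library labelled HFD_shYap.

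Different phagocyte clusters dominated each library. Cluster 4 held 42.3% of the phagocytes of LFD_WT, cluster 21 held 37.1% in LFD_shYap, cluster 2 held 38.2% in HFD_WT and cluster 9 held 28.1% in HFD_shYap. Cluster 21 was almost a single-library cluster, with 2151 cells from LFD_shYap and 22, 41 and 40 from LFD_WT, HFD_WT and HFD_shYap. Phagocyte values are sums over all these clusters, so they carry both the mix of clusters and the levels within them. The T lineage differed likewise: its largest sub-cluster was 2 in LFD_WT and LFD_shYap (165 of 619 and 124 of 648 cells), 1 in HFD_WT (176 of 1143) and 10 in HFD_shYap (250 of 886).

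Across both tumour lines, phagocytes of the high-fat libraries had higher RNA for Cxcl9, Nos2 and MHC class II presentation genes and lower RNA for Tnf, Ccl3 and Ccl4. Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), a chemokine that attracts CXCR3-bearing T cells, rose by a log2 fold change of 2.52 (SE 0.208, edgeR adjusted p = 0.000248). Its levels were 40.6 and 36.5 CPM in LFD_WT and LFD_shYap and 288 and 183 CPM in HFD_WT and HFD_shYap. Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), the inducible nitric oxide synthase, rose by 3.19 (SE 0.264, edgeR adjusted p = 0.000248). Ndrg1, a hypoxia-responsive gene, rose by 1.67 (SE 0.161, edgeR adjusted p = 0.000457). Of the other genes with the smallest p-values, Itgax (2.04), H2-M2 (5.47), Ass1 (1.97), C3 (1.58), Upp1 (2.36) and Dnase1l3 (2.55) rose, and the granzyme gene Gzmf changed by -4.09, with its highest level in NK cells. In all, 75 genes rose and 39 fell of 14179 tested, with 907 at an unadjusted edgeR p under 0.05. Of these 114 genes, 50 had at least 5 times higher CPM in another cell type, 41 of the 75 that rose and 9 of the 39 that fell.

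The MHC class II presentation list rose with high-fat diet in phagocytes: 4 of its 9 members rose over all genes tested and 8 when adjusted over the list alone, with a median log2 fold change of 1.30. H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419), H2-Eb1, H2-Aa and the transactivator gene Ciita rose by 1.65, 1.64, 1.62 and 1.30. The camera adjusted p was 2.47e-27 with the preset correlation, and adjusted p = 0.479 with an estimated correlation, a value shared by the phagocyte diet lists called with the preset correlation unless another is given. H2-Ab1, H2-Eb1, H2-Aa and Cxcl9 are among the genes that lead phagocyte cluster 2. It held 12.3%, 14.3%, 38.2% and 23.8% of the phagocytes of LFD_WT, LFD_shYap, HFD_WT and HFD_shYap. Of 13 hypoxia and glycolysis genes, 4 rose over all genes and 8 adjusted over the list alone (median 0.58, camera adjusted p = 7.6e-25), among them Ero1l (1.10), Vegfa (1.02) and the glucose transporter Slc2a1 (0.96). Of 12 classically activated (M1) macrophage genes, 3 rose and 1 fell, against 7 and 1 adjusted over the list alone (median 0.53, camera adjusted p = 2.7e-14). Nos2, Cxcl9 and Ptgs2 (0.93) rose while Tnf changed by -0.92. Cholesterol and fatty acid synthesis had 1 of 12 members up, Sqle at 1.05, and 6 adjusted over the list alone (median 0.43, camera adjusted p = 3.43e-09). Complement and resident macrophage genes were lower, with 1 of 10 down, Vsig4 at -1.40, and 4 adjusted over the list alone (median -0.48, camera adjusted p = 2.55e-12). NF-kB and inflammatory cytokine genes had 3 of 12 down, Tnf, Ccl3 (-1.48) and Ccl4 (-1.41), and 6 down with 1 up adjusted over the list alone (median -0.36, camera adjusted p = 3.03e-11). Alternatively activated (M2) macrophage genes moved both ways and were not called (camera adjusted p = 0.69), with Retnla (4.92) and Mgl2 (1.77) up and Cd163 (-2.13) and Chil3 (-1.22) down.

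Other phagocyte lists gave less stable diet calls. Checkpoint ligands had 2 of 9 members up, Pdcd1lg2 (2.13) and Cd274 (1.02), and 3 adjusted over the list alone (median 0.31, camera adjusted p = 1.51e-05), with camera adjusted p = 0.051 when the treatment field set the diet and 0.679 without genes of other cell types. Chemokines had 2 of 13 up and 2 down, or 3 and 6 adjusted over the list alone (median -0.54, camera adjusted p = 0.0138). Their adjusted p = 0.573 with an estimated correlation, and the preset call was lost at 0.977, 0.13 and 0.979 without LFD_WT, HFD_WT or HFD_shYap. Markers of other sources moved too: free hepatocyte RNA had a median of -0.67 (camera adjusted p = 0.00678) and free erythrocyte RNA of -2.06 (camera adjusted p = 0.000595, adjusted p = 0.573 with an estimated correlation). The hepatocyte call was lost at 0.259, 0.0506 and 0.121 without LFD_WT, HFD_WT or HFD_shYap, and the erythrocyte call turned upward at 0.0306 without HFD_shYap. The interferon response (0.359), lipid-associated macrophage (0.203), cell cycle (0.359), dissociation stress (0.0799), YAP target (0.434), oxidative phosphorylation (0.374) and fatty acid oxidation (0.91) lists had camera adjusted p-values above the threshold. The count of 114 genes became 2 without HFD_WT, with none of the 114 kept, 13 without HFD_shYap, 345 without LFD_WT and 0 with the diet of LFD_shYap from its treatment field. It was 26 with diet alone in the model, 52 without doublet removal, 320 without the expression filter and 17 with only the Xist-bearing cells of HFD_shYap.

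**Figure D3:**
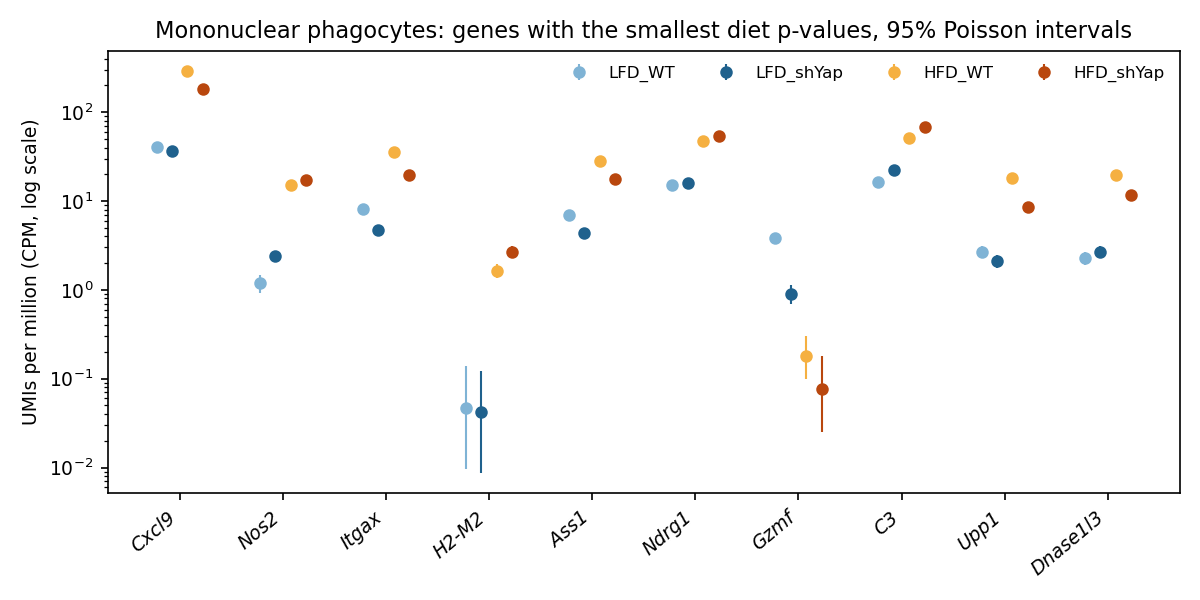
CPM (log axis) in mononuclear phagocytes of the 4 libraries for the 10 genes with the smallest diet p-values; points are library values and lines exact 95% Poisson intervals. Cxcl9 stood at 40.6 and 36.5 CPM in the low-fat and 288 and 183 CPM in the high-fat libraries.

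In the T lineage, high-fat diet came with higher regulatory and hypoxia genes and lower naive and memory genes. Of 9 regulatory T cell genes, Foxp3 (1.09), the lineage-defining factor, and Icos (1.02) rose over all genes tested and 4 adjusted over the list alone (median 0.49, camera adjusted p = 9.72e-08). The regulatory sub-cluster 9 held a similar share of T lineage cells in HFD_WT (90 of 1143) and LFD_WT (47 of 619). Its share differed between HFD_shYap (75 of 886) and LFD_shYap (34 of 648), the pair with the conflicting diet label. Foxp3 leads this sub-cluster, and its log2 ratio in that pair, given below, was larger than its change over both lines. Of 9 naive and memory genes, the factors Lef1 (-0.81) and Klf2 (-0.73) fell, and 4 adjusted over the list alone (median -0.53, camera adjusted p = 1.2e-06, and 0.0798 without LFD_WT). Hypoxia and glycolysis had 1 member up, Bnip3 at 1.04, and 8 adjusted over the list alone (median 0.49, camera adjusted p = 3.44e-10). The exhaustion and inhibitory receptor list had Ctla4 (0.89) up, also adjusted over the list alone (median 0.33, camera adjusted p = 0.000796, and 0.709 without LFD_WT). In the cytotoxicity list, the granzymes Gzmf (1.42) and Gzmc (1.22) and the receptor Klrg1 (1.48) rose and Gzma (-1.42) fell, with the same counts of 3 and 1 adjusted over the list alone (median 0.33, camera adjusted p = 0.00214). That call was lost at 0.285 without LFD_WT and 0.117 without HFD_WT, and turned downward at 0.0484 without doublet removal. All these lists had adjusted p = 0.63 with an estimated correlation.

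The T lineage genes with the smallest diet p-values were Slc17a6, a vesicular glutamate transporter gene (log2 fold change 2.44, SE 0.267, edgeR adjusted p = 1.43e-07), and Ifitm1 (1.92, SE 0.212, edgeR adjusted p = 1.43e-07). Slc17a6 was at 3.23 and 6.30 CPM in LFD_WT and LFD_shYap and 24.8 and 29.99 CPM in HFD_WT and HFD_shYap. Dgat1 (1.43) and Klri2 (1.76) also rose. The mast cell protease genes Tpsb2 (-3.50) and Cma1 (-3.53), which led an unnamed T sub-cluster with a median of 981.5 UMIs, fell, as did Gzma, Saa3 (-1.74) and the macrophage apolipoprotein gene Apoe (-1.32). Chemokines had 1 of 13 up, Cxcl9 at 2.17, and 7 down, or 2 and 9 adjusted over the list alone (median -0.73, camera adjusted p = 1.71e-12, adjusted p = 0.63 with an estimated correlation). That call was lost at 0.331 without LFD_WT and 0.439 without HFD_shYap. Macrophage markers in T lineage cells were at 11.95%, 6.05%, 9.27% and 5.08% of their phagocyte level in LFD_WT, LFD_shYap, HFD_WT and HFD_shYap. At that percentage of its phagocyte level Cxcl9 would stand at 4.85, 2.21, 26.7 and 9.28 CPM, and it was measured at 4.52, 2.42, 21.5 and 11.2 CPM. The preset correlation also called NF-kB and inflammatory cytokine genes (median -0.17, camera adjusted p = 0.000235), cholesterol and fatty acid synthesis (0.28, 0.00995), cell cycle (-0.21, 0.026) and oxidative phosphorylation (-0.13, 0.026), with adjusted p = 0.715 for the last and 0.63 for the others with an estimated correlation. The NF-kB call was lost at 0.306 and 0.0891 without LFD_WT or HFD_WT, and that of cholesterol synthesis at 0.0995 and 0.161 without LFD_shYap or HFD_shYap. Without LFD_WT, LFD_shYap or HFD_shYap, cell cycle was at 0.057, 0.201 and 0.618 and oxidative phosphorylation at 0.134, 0.169 and 0.618. In all 66 genes rose and 61 fell of 10631 tested, with 970 at an unadjusted edgeR p under 0.05. Of these 127, 60 had at least 5 times higher CPM in another cell type, 40 of them in phagocytes. The count was 28 without HFD_shYap, 77 without LFD_WT, 68 without HFD_WT, 39 with the treatment field, 24 by DESeq2, 2 with diet alone in the model and 66 without genes of other cell types. Apoe was not called without HFD_shYap (-0.70), Gzma was not called with only the Xist-bearing cells of that library (-0.74), and Tpsb2 and Cma1 were not called by DESeq2.

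In neutrophils, hypoxia and suppressive genes were higher with high-fat diet as lists, while no single gene passed the test. All 12 measured hypoxia and glycolysis genes gave a median of 1.27 (camera adjusted p = 1.14e-17), with 0 past the threshold over all genes and 11 up adjusted over the list alone. Ero1l (2.12) and the mitophagy gene Bnip3 (2.03) both had an edgeR adjusted p of 0.107. Of 12 tumour neutrophil and suppressive genes, 0 passed over all genes and 7 rose adjusted over the list alone (median 1.11, camera adjusted p = 1.45e-09), with Cxcl3 at 3.11, Ccl3 at 2.61 and the checkpoint ligand gene Cd274 at 2.35. The neutrophil maturation and granule genes had a median of -0.98 (camera adjusted p = 0.00546, and 0.0559 without LFD_shYap), cell cycle -1.05 (0.00491, and 0.832 without LFD_shYap) and oxidative phosphorylation -0.63 (0.000128). Dissociation stress genes, a sign of handling, moved up with them (median 0.72, camera adjusted p = 0.00318). So did interferon response (1.01, 0.000102, and 0.059 without HFD_shYap), NF-kB and inflammatory cytokine genes (0.75, 6.4e-05, and 0.449 without LFD_shYap) and checkpoint ligands (0.37, 0.00318, and 0.131 without LFD_shYap). Chemokines (0.69, 0.00491) were lost at 0.27 and 0.258, and YAP target genes (0.33, 0.0312) at 0.27 and 0.156, without LFD_shYap or HFD_WT. All of these lists had adjusted p = 0.592 with an estimated correlation. By edgeR 0 of 6505 genes passed, with 743 at an unadjusted p under 0.05, and DESeq2 called 19. On simulated data the edgeR test recovered 0 of 100 genes changed 4-fold here, so the count of 0 does not show absence of change. The count was 246 without LFD_WT, 103 without LFD_shYap and 88 without doublet removal, and the suppressive list call was lost at 0.142 with the treatment field.

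Across both diets, 5 genes rose and 1 fell in phagocytes of the libraries labelled shYap. None was called with line alone in the model, the model that every fit with a library left out also used. Clec4f (ENSMUSG00000014542, chromosome 6, 83644542 to 83656187), a Kupffer cell lectin, rose by 1.94 (SE 0.201, edgeR adjusted p = 0.00603), from 4.39 and 2.36 CPM in LFD_WT and HFD_WT to 16.6 and 9.38 CPM in LFD_shYap and HFD_shYap. Cd5l (ENSMUSG00000015854, chromosome 3, 87357881 to 87371073), a secreted macrophage protein, rose by 1.19 (SE 0.166, edgeR adjusted p = 0.0337), and Apoc1 by 1.30 (SE 0.163, edgeR adjusted p = 0.0225). With only the cells of HFD_shYap that carried Y-linked UMIs, the changes were 0.36 for Clec4f and 0.34 for Cd5l. These genes lead phagocyte cluster 22, which held 19, 39, 10 and 27 cells in LFD_WT, LFD_shYap, HFD_WT and HFD_shYap. Zbtb16 (ENSMUSG00000066687, chromosome 9, 48654297 to 48836222) rose by 2.35 (SE 0.321, edgeR adjusted p = 0.0337) and Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527) by 1.35 (SE 0.191, edgeR adjusted p = 0.0337). Fkbp5, a chaperone of the glucocorticoid receptor, stood at 65.7 and 57.1 CPM in the WT and 194 and 127 CPM in the libraries labelled LFD_shYap and HFD_shYap. The immunoglobulin gene Iglc1 changed by -2.55 (SE 0.372, edgeR adjusted p = 0.0365).

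These were 5 genes up and 1 down of 14179, with 964 at an unadjusted edgeR p under 0.05, and 2 up and 0 down with RLE size factors. All 6 calls were lost with line alone in the model, with the treatment field and without doublet removal, while DESeq2 called 27 genes and the unfiltered test 153. Fits that left a library out also had line alone, so they do not separate the effect of the library from that of the model. Of 13 cell cycle genes, 0 passed over all genes and 8 fell adjusted over the list alone (median -0.46, camera adjusted p = 2.08e-11), and oxidative phosphorylation had a median of -0.25 (camera adjusted p = 0.000105). Complement and resident macrophage genes had 2 up, Clec4f and Cd5l, and 3 adjusted over the list alone (median 0.02, camera adjusted p = 8.84e-06), and this complement and resident macrophage genes call was lost at 0.745 and 0.342 without LFD_shYap or HFD_WT and at 0.988 with Y-linked cells only. The preset camera calls of the M1 (median -0.27, 0.000616), lipid-associated macrophage (-0.20, 0.00299), chemokine (-0.30, 8.67e-05), cholesterol (-0.12, 0.0173) and free erythrocyte (-2.04, 0.000232) lists each had adjusted p = 0.693 with an estimated correlation, as did those before them. For the interferon response (-0.28, camera adjusted p = 0.00131), adjusted p = 0.701 with an estimated correlation. Leaving out LFD_shYap or HFD_WT ended the call of the classically activated (M1) macrophage genes (camera adjusted p = 0.582 and 0.398), the lipid-associated macrophage genes (0.251 and 0.0678) and cholesterol and fatty acid synthesis (0.582 and 0.885). The interferon response was lost without LFD_WT or LFD_shYap (0.751 and 0.27), chemokines without LFD_WT or HFD_shYap (0.39 and 0.0649) and free erythrocyte RNA without HFD_WT or HFD_shYap (0.104 and 0.138).

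In the T lineage of the libraries labelled shYap, chemokine, interferon and macrophage genes were lower. Mcpt2 (ENSMUSG00000022226, chromosome 14, 56042041 to 56044642), a mast cell protease gene, changed by -4.13 (SE 0.364, edgeR adjusted p = 4.25e-10), with 112 and 53.5 CPM in LFD_WT and HFD_WT, 12.8 CPM in LFD_shYap and 0 UMIs in HFD_shYap. With the mast cell genes Cma1, Tpsb2 and Cpa3 it leads the unnamed T sub-cluster 1, which held 103, 103, 176 and 112 cells in LFD_WT, LFD_shYap, HFD_WT and HFD_shYap at a median of 981.5 UMIs. Ccl12, a monocyte-attracting chemokine, changed by -2.15 (SE 0.198, edgeR adjusted p = 8.27e-10), and the genes Il1b (-2.09), Ccl2 (-1.69), Pf4 (-1.51), Cxcl10 (-1.41), Cxcl2 (-1.30), Lyz2 (-1.23) and Apoe (-1.05) fell with it. Gm42418, a locus that overlaps ribosomal RNA sequence and is therefore uncertain, rose by 1.07. Of 13 chemokines, 9 fell over all genes and 11 adjusted over the list alone (median -0.96, camera adjusted p = 1.26e-43). Of 11 interferon response genes, 3 fell, Ifit3 (-1.203), Isg15 (-1.02) and Bst2 (-0.73), and 8 adjusted over the list alone (median -0.71, camera adjusted p = 9.69e-13). Of 11 NF-kB and inflammatory cytokine genes, 4 fell by either adjustment (4 adjusted over the list alone, median -0.31, camera adjusted p = 2.43e-07), and that call was lost at 0.399 without LFD_WT and 0.137 without doublet removal. All 3 lists had adjusted p = 0.819 with an estimated correlation. The exhaustion (0.0548), cytotoxicity (0.376), naive and memory (0.195) and regulatory T cell (0.686) lists had camera adjusted p-values above the threshold.

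In all, 13 T lineage genes rose and 145 fell of 10631, with 850 at an unadjusted edgeR p under 0.05. Of these 158, 133 had at least 5 times higher CPM in another cell type, 111 of them in phagocytes. Phagocyte RNA was estimated at 11.95%, 6.05%, 9.27% and 5.08% of T lineage UMIs in LFD_WT, LFD_shYap, HFD_WT and HFD_shYap. The count was 0 without HFD_shYap, 11 without LFD_shYap, 52 without LFD_WT, 0 with line alone in the model, 53 with the treatment field, 41 by DESeq2, 17 without doublet removal, 83 with only the Xist-bearing cells of HFD_shYap and 12 without genes of other cell types. Without HFD_shYap, Mcpt2, Ccl12, Gm42418 and Apoe changed by -2.63, -1.98, 0.21 and -0.33 and were not called. Apoe and Lyz2 were at -0.32 and -0.71 without LFD_WT and at -0.12 and -0.34 without doublet removal, again not called, and DESeq2 did not call Mcpt2.

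**Figure D4:**
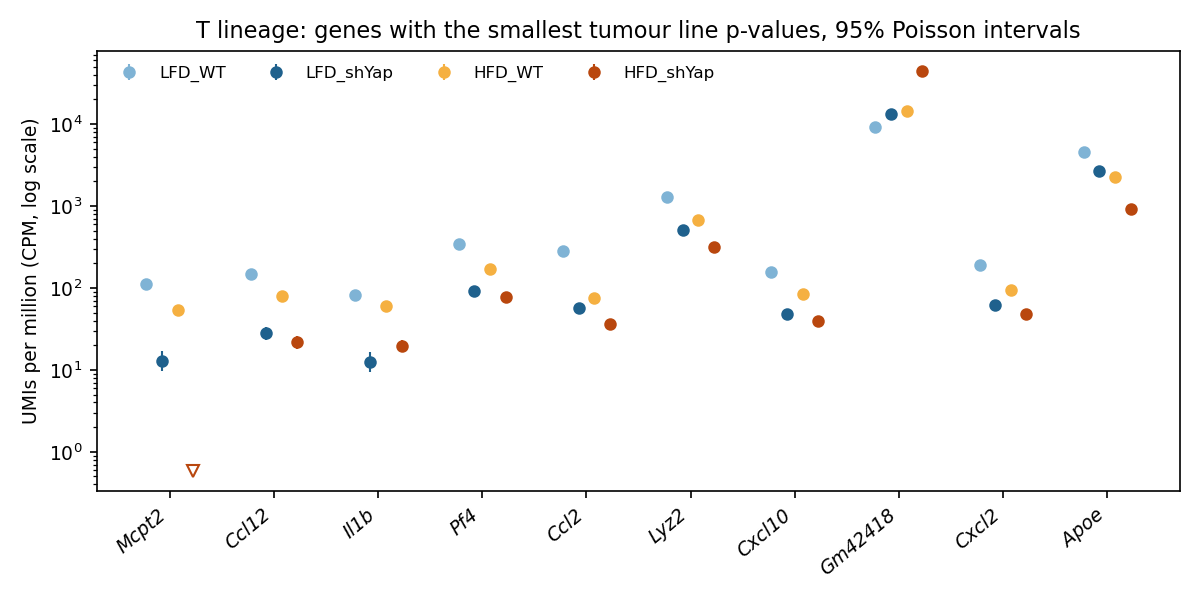
CPM (log axis) in the T lineage of the 4 libraries for the 10 genes with the smallest tumour line p-values; points are library values, lines exact 95% Poisson intervals, and the open triangle an upper bound for a count of 0. Mcpt2 stood at 112 and 53.5 CPM in the WT libraries and 12.8 CPM in LFD_shYap.

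In neutrophils of the libraries labelled shYap, chemokine RNA was lower as a list, and so were macrophage markers. The median CPM of 10 macrophage markers in neutrophils was 32.9%, 15.8%, 25.01% and 16.7% of that in phagocytes in LFD_WT, LFD_shYap, HFD_WT and HFD_shYap. At that percentage of its phagocyte level Ccl12 would stand at 269, 48.1, 115 and 43.9 CPM, and it was measured at 394, 59.7, 205 and 59.8 CPM in neutrophils. Of 13 chemokines, 0 passed over all genes and 5 fell adjusted over the list alone (median -1.23, camera adjusted p = 2.31e-13), with log2 fold changes of -2.14 for Ccl12, -1.91 for the interferon-inducible Cxcl10 and -1.60 for Ccl2. The neutrophil maturation and granule genes had a median of 0.91 (camera adjusted p = 1.44e-05, and 0.457 without LFD_shYap), NF-kB and inflammatory cytokine genes -0.49 (0.000201, and 0.462 without LFD_shYap) and tumour neutrophil and suppressive genes -0.46 (0.00888, and 0.0792 and 0.686 without LFD_shYap or HFD_WT). Oxidative phosphorylation (-0.30, 0.0168) was lost at 0.557 and 0.847 without LFD_WT or HFD_shYap, and cell cycle (0.52, 0.0477) turned downward at 0.032 without LFD_shYap. All of these lists had adjusted p = 0.744 with an estimated correlation. By edgeR 0 of 6505 genes passed, with 330 at an unadjusted p under 0.05, and DESeq2 called 0. The count was 70 without HFD_shYap and 12 without doublet removal.

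HFD_WT was set against LFD_WT to describe diet with the WT tumour line, with 1 library on each side and so no test. In phagocytes, dominated by cluster 2 in HFD_WT and cluster 4 in LFD_WT, the 4 highest ratios among genes with at least 50 CPM in the higher library included Cxcl9 and H2-Ab1, and the 4 lowest were those of Lyve1, Cd163, Ccl24 and Ltc4s. Cxcl9 was at 288 against 40.6 CPM (log2 ratio 2.83, interval 2.77 to 2.89), H2-Ab1 at 2211 against 448 CPM (2.30), H2-Eb1 at 2113 against 431 CPM (2.29) and H2-Aa at 2048 against 459 CPM (2.16). Lyve1 (ENSMUSG00000030787, chromosome 7, 110850607 to 110863239), a hyaluronan receptor of tissue-resident macrophages, was at 23.6 against 174 CPM (-2.88). The haemoglobin scavenger receptor Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527) was at 7.85 against 52.3 CPM (-2.74), Ccl24 at 27.9 against 147 CPM (-2.39) and Ltc4s at 82.5 against 290 CPM (-1.81). Cxcl9, H2-Ab1, H2-Eb1 and H2-Aa are among the genes that lead cluster 2, with 38.2% against 12.3% of phagocytes. Lyve1, Cd163 and Ltc4s are among those that lead cluster 4, with 8.87% against 42.3%. These ratios therefore carry the mix of clusters. Relative to the all-gene median, all 9 MHC class II presentation genes were above it (median 1.62, percentile 100 among 10000 matched random lists), as were all 13 hypoxia and glycolysis genes (0.64, percentile 100). Chemokines (-0.63), interferon response (-0.48) and NF-kB genes (-0.47) were each at percentile 0.

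T lineage cells of HFD_WT had all 9 naive and memory genes under the all-gene median (-0.80, percentile 0), among them S1pr1 at 20.7 against 45.5 CPM and Tcf7 at 20.1 against 41.4 CPM. Exhaustion and inhibitory receptors had a median of 0.57 (percentile 100), with Pdcd1 at 319 against 166 CPM, Ctla4 at 225 against 109 CPM and Havcr2 at 35.7 against 17.1 CPM. Prss2 (ENSMUSG00000057163, chromosome 6, 41521787 to 41525079), a trypsinogen gene within the T cell receptor beta locus, had 702 UMIs (114 CPM) against 2 UMIs (log2 interval 5.61 to 10.52). Gzmf was at 87.5 against 14.9 CPM (2.56), but its ratio turned to -2.63 without doublet removal. Ifitm1 was at 70.8 against 18.7 CPM (1.92), Ccl2 at 74.5 against 280 CPM (-1.91, with 37.7 against 155 CPM at the macrophage marker percentages of 9.27% and 11.95%), Tpsb2 at 18.3 against 81.7 CPM (-2.16) and Cma1 at 18.6 against 81.7 CPM (-2.14). In neutrophils, all 12 hypoxia and glycolysis genes lay above the median (1.54, percentile 100), with Ero1l at 780 against 154 CPM (2.35) and Bnip3 at 540 against 113 CPM (2.25), and dissociation stress genes had a median of 0.52 (percentile 99.16). Nos2 had 116 UMIs against 3 (log2 interval 2.16 to 6.04), the tight junction gene Cldn1 172 against 1 (3.40 to 11.21), and Egr3 was at 10.1 against 136 CPM (-3.75). In all, 28 of 46 lists lay outside the central 95% of their random lists.

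The library labelled HFD_shYap was set against HFD_WT for the knockdown under high-fat diet, where Yap1 RNA did not follow the label. Phagocytes, with cluster 9 the largest in HFD_shYap and cluster 2 in HFD_WT, had all 9 MHC class II presentation genes under the all-gene median (-0.53, percentile 0), with H2-Ab1 at 1428 against 2211 CPM (-0.63) and the invariant chain gene Cd74 at 3765 against 5546 CPM (-0.56). Sex-linked RNA of HFD_shYap differed between these clusters. Y-linked RNA was at 115% of the mean of the other libraries in cluster 9 and 68.8% in cluster 2, with Xist at 190 and 440 CPM. Cell cycle genes had a median of -0.44 (percentile 0) and alternatively activated (M2) macrophage genes of 0.30 (percentile 99.9), with Cd163 at 18.1 against 7.85 CPM (1.21) and Retnla at 3.22 against 0.295 CPM (3.45). Among genes with at least 50 CPM and 30 UMIs in the higher library, the mitochondrial leucyl-tRNA synthetase gene Lars2 was at 496 against 170 CPM (1.55) and Fkbp5 at 127 against 57.1 CPM (1.16). The neutrophil genes S100a9 and S100a8 were at 9.45 against 61.4 CPM (-2.70) and 24.2 against 84.2 CPM (-1.80).

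In the T lineage of the library labelled HFD_shYap, chemokines (-0.93) and interferon response genes (-0.55) were at percentile 0, with Isg15 at 105 against 204 CPM (-0.96), while NF-kB genes had a median of 0.35 (percentile 99.87). Macrophage markers in T lineage cells were at 5.08% against 9.27% of their phagocyte level in this pair. At 9.27% of its phagocyte level Isg15 would stand at 22.5 CPM in HFD_WT, where it was measured at 204 CPM. Lars2 was at 832 against 214 CPM (1.96) and the NF-kB inhibitor gene Nfkbiz at 65.4 against 28.5 CPM (1.197). Mcpt2 had 0 UMIs against 328, a log2 ratio of at most -6.50 with the counting error of both libraries, and Prss2 was at 2.39 against 114 CPM (-5.58). Neutrophils had 10 of 11 interferon response genes above the all-gene median (1.23, percentile 100), with Ifit1 at 793 against 195 CPM (2.03, interval 1.85 to 2.20) and the RNA sensor gene Ifih1 at 112 against 26.4 CPM (2.09). Their heat shock genes Hspa1a and Hspa1b were at 74.5 against 376 CPM (-2.34) and 88.3 against 416 CPM (-2.24). In all, 14 of 46 lists lay outside the central 95%.

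The library labelled LFD_shYap was set against LFD_WT for the knockdown under low-fat diet, as titled. By its treatment field the pair would differ in diet too, and these values could not separate diet from line. Phagocytes, with cluster 21 the largest in LFD_shYap and cluster 4 in LFD_WT, had all 13 cell cycle genes (median -0.52, percentile 0) and all 11 interferon response genes (-0.47, percentile 0) under the all-gene median, with Isg15 at 202 against 352 CPM (-0.80). MHC class II presentation (0.60, percentile 100) and complement and resident macrophage genes (0.39, percentile 99.92) were higher, with Clec4f at 16.6 against 4.39 CPM (1.91) and the scavenger receptor gene Marco at 101 against 47.0 CPM (1.11). Ccl24 was at 15.6 against 147 CPM (-3.23), the secreted phosphoprotein gene Spp1 at 457 against 1313 CPM (-1.52) and Ccl12 at 304 against 818 CPM (-1.43). Genes that lead cluster 21 were also among the highest ratios at 50 CPM or more, such as Jaml at 167 against 26.1 CPM (2.68) and Pnpla2 at 110 against 35.5 CPM (1.63).

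T lineage cells of the library labelled LFD_shYap had chemokines (-1.05), NF-kB genes (-0.81) and interferon response genes (-0.77) at percentile 0, with Il1b at 12.6 against 81.4 CPM (-2.69) and Ccl12 at 28.1 against 149 CPM (-2.41), while macrophage markers in T lineage cells were at 6.05% against 11.95% of their phagocyte level. At those percentages the interferon response gene Isg15 would stand at 12.2 against 42.1 CPM, and it was measured at 99.8 against 208 CPM. Exhaustion and inhibitory receptors were higher (0.41, percentile 100), with Havcr2 at 36.3 against 17.1 CPM (1.09) and Pdcd1 at 256 against 166 CPM (0.62). Mcpt2 was at 12.8 against 112 CPM (-3.12), and Gzmf at 61.8 against 14.9 CPM (2.06) turned to -2.47 without doublet removal. In neutrophils, granule genes (2.53) and cell cycle genes (2.34) were at percentile 100, with the antimicrobial peptide genes Camp at 9609 against 163 CPM (5.88) and Ngp at 11460 against 295 CPM (5.28). Elane had 143 UMIs against 0, a log2 ratio of at least 4.81 with the counting error of both libraries. These genes lead neutrophil cluster 25, to which LFD_shYap gave 34 of its 44 cells. Chemokines (-1.61), NF-kB (-1.19) and suppressive genes (-0.98) were at percentile 0, with Cxcl10 at 27.3 against 248 CPM (-3.18), while macrophage markers in neutrophils were at 15.8% against 32.9% of their phagocyte level. In all, 26 of 45 lists lay outside the central 95%.

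The library labelled HFD_shYap was also set against LFD_shYap, as a secondary comparison because of the conflicting diet label. Phagocytes, with cluster 9 the largest in HFD_shYap and cluster 21 in LFD_shYap, had higher MHC class II presentation (0.93), classically activated (M1) macrophage (0.68), checkpoint ligand (0.62) and hypoxia and glycolysis genes (0.49), each at percentile 100. Nos2 was at 17.1 against 2.38 CPM (2.85), Cxcl9 at 183 against 36.5 CPM (2.32) and H2-Aa at 1541 against 676 CPM (1.19). All 10 complement and resident macrophage genes were under the all-gene median (-0.71, percentile 0), with Marco at 28.02 against 101 CPM (-1.85) and Vsig4 at 23.4 against 58.4 CPM (-1.32). In the T lineage, all 9 regulatory T cell genes were above it (0.37, percentile 99.78), with Foxp3 at 24.9 against 5.09 CPM (2.29, interval 1.63 to 3.02) and Il2ra at 59.8 against 20.6 CPM (1.54). The regulatory sub-cluster 9, which Foxp3 and Il2ra lead, held 75 of 886 against 34 of 648 T lineage cells, the CD4 sub-cluster 8 held 148 against 26 and sub-cluster 10 held 250 against 40. In HFD_WT against LFD_WT, sub-cluster 9 held 90 of 1143 against 47 of 619 cells, a similar share. In neutrophils, suppressive (2.02), interferon response (1.87), NF-kB (1.41) and hypoxia genes (1.33) were at percentile 100 and granule genes (-1.82) at percentile 0, with Cxcl3 at 2663 against 173 CPM (3.94) and Camp at 196 against 9609 CPM (-5.62). In all, 25 of 46 lists lay outside the central 95%.

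**Figure D5:**
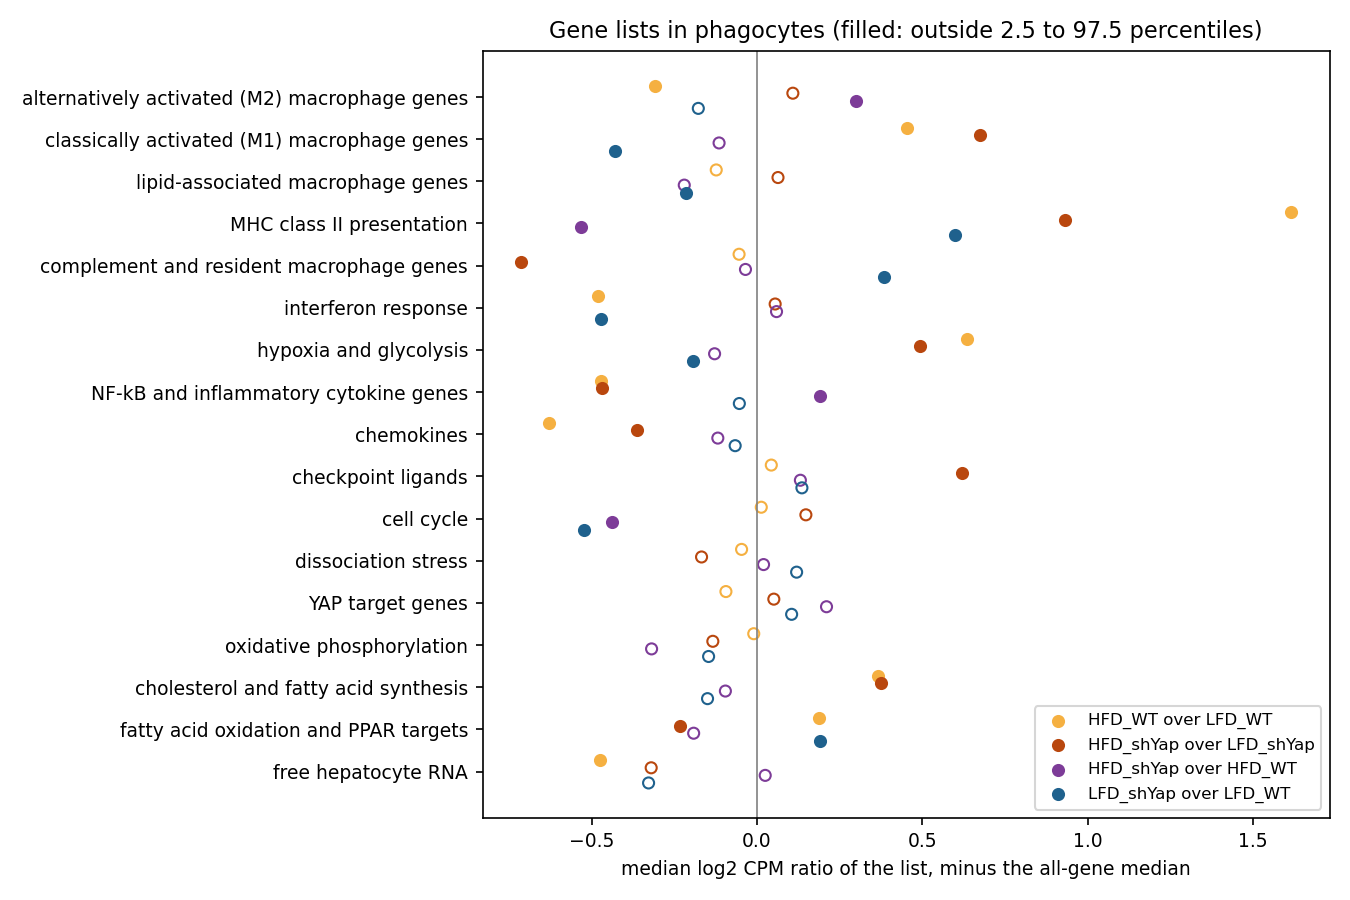
Median log2 CPM ratio of each gene list in mononuclear phagocytes, relative to the all-gene median, for 4 pairs of libraries; filled points lie outside the central 95% of matched random lists. MHC class II presentation ran from -0.53 for HFD_shYap against HFD_WT to 1.62 for HFD_WT against LFD_WT.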

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

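Tests chosen only after their result was seen were those of mixed sexes, of the diet calls without Xist-bearing cells, of stromal cells and of a mislabelled sample; the tests of YAP target genes and of phagocyte RNA were set before.

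Xist stood at 354.8 CPM over all kept cells of the library labelled HFD_shYap, a level not seen in the other 3 libraries, whose cells held 2, 3 and 8 UMIs. Among 4162 phagocytes of this library thinned to 5000 UMIs, 108 had both Xist and Y-linked UMIs where 507 would be expected from independent detection, a ratio of 0.213, which is consistent with a mix of cells from female and male mice. The idea that the Xist-bearing cells account for the diet calls in phagocytes was argued against, since 107 of the 114 genes were kept with only the Y-linked cells of that library. For the tumour line, 4 of the 6 phagocyte calls and 143 of the 158 T lineage calls were kept with these cells, while the log2 fold changes of Clec4f and Cd5l in phagocytes, 1.94 and 1.19 with all cells, were 0.36 and 0.34. Sex of the mice thus stays open as a source of part of the tumour line differences, and the labels give no sex by which to test it.

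Yap1, in clusters 1 and 14 that the comparisons between lineages did not use, stood at 21.01, 18, 16.9 and 21.9 CPM in LFD_WT, LFD_shYap, HFD_WT and HFD_shYap, above the limit that a count of 0 allows. That these clusters are stromal cells of the mice was argued against by their Y-linked RNA, which reached at most 6.74% of the phagocyte level in the 3 libraries without Xist, although cluster 14 carries fibroblast markers; in HFD_shYap, Y-linked RNA was at 1.89% and 9.57% and Xist at 0% and 10.7% of that level in clusters 1 and 14. Whether Yap activity was lowered without lower Yap1 RNA was not decided over both diets, since the YAP target list went opposite ways. Under high-fat diet its median was 0.36 (10 of 12 members above the all-gene median, percentile 99.98), which is not the direction of lowered activity. Under low-fat diet it was -0.27 (3 of 12 above, percentile 0.53), so lowered activity may still apply there. Each value rests on 1 library on each side. A mislabelled sample cannot be told apart from a knockdown that acts on protein, since no other value shows the line of a library and the lowest ratio of Yap1 between lines was 0.857.

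Macrophage genes were lower in T lineage cells of the libraries labelled shYap, and phagocyte RNA in T cell droplets is a candidate explanation. Of the 111 called genes with at least 5 times higher CPM in phagocytes, 94.6% lay within 0.5 of the log2 change predicted from the phagocyte profile and 1 common share of phagocyte RNA per library. That share was 11.95% and 9.27% in LFD_WT and HFD_WT and 6.05% and 5.08% in LFD_shYap and HFD_shYap. It was set from macrophage markers, of which Apoe, C1qa, C1qb, C1qc, Csf1r, Cd68, Trem2 and Ms4a7 were among the genes scored. All scored genes had also been picked for being called, with a median change of -1.06 against -1.01 predicted. The percentage within 0.5 was therefore partly set in advance. Without genes of other cell types, 12 genes changed with line in the T lineage, against 158 with them. An effect of the tumour line on the T cells themselves stays open for the genes outside this set.

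Several lists moved in opposite directions under the 2 diets or with the 2 lines, and none of these differences was tested. For tumour line, the list median under high-fat minus that under low-fat diet was -1.13 for MHC class II presentation in phagocytes (-0.53 and 0.60). It was -8.60 for free erythrocyte RNA in phagocytes (-7.42 and 1.18), but without doublet removal the low-fat value turned to -0.40, the direction of the other. It was 1.17 for NF-kB and inflammatory cytokine genes in the T lineage (0.35 and -0.81). In neutrophils it was 2.12 for the interferon response (1.23 and -0.89) and -3.13 for cell cycle (-0.79 and 2.34). For diet, the median with WT minus that with shYap tumours was 0.42 for fatty acid oxidation in phagocytes (0.19 and -0.23) and 8.49 for free erythrocyte RNA there (1.14 and -7.35), where 1.14 turned to -1.29 without doublet removal. In neutrophils it was 2.57 for granule genes (0.75 and -1.82) and 3.42 for cell cycle (0.74 and -2.68).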

How the results depend on the processing

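Alternatives chosen only after the data were seen were those with Xist-bearing or Y-linked cells of HFD_shYap only, without genes of other cell types, without T sub-cluster 1, with T and NK cells counted together, and with the low-depth cluster counted as phagocytes; all others were set before. No pairing of replicates was possible because there was 1 library per combination and the labels give no shared replicate numbers. The additive model did compare each factor within the levels of the other. Of the log2 fold changes of named genes, 324 of 468 kept their direction and call and 144 kept their direction but lost the call; of list tests 492 of 596 kept both, 101 lost the call and 3 turned. Among ratios without a test, 2576 of 3050 stayed within their counting interval, 447 moved and 27 turned, and for list medians these were 416, 57 and 4 of 477. Counts of lists outside their percentiles stayed within 1.5 times in 20 of 20 cases. Among the 3 tested lineages, low depth limits neutrophil values most. Unless the setting leaves out genes, the cause was not tested. Fits without a library also dropped the other factor from the model. With all libraries, dropping that factor alone took the phagocyte counts from 6 to 0 for line and from 114 to 26 for diet. In the T lineage it took them from 158 to 0 and from 127 to 2.

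In phagocytes, 6 genes changed with line, against 27 with DESeq2, 2 with RLE size factors, 153 with no filter, 0 with line alone, 0 with diet from the treatment field, 0 without doublet removal, 10 with Y-linked and 1 with Xist-bearing cells only, 22 without genes of other cell types, and 0 to 0 over the libraries left out. With diet 114 changed, against 320 with no filter, 26 with diet alone, 0 with the treatment field, 52 without doublet removal, 17 with Xist-bearing cells only, and 2 to 345 over the libraries left out. In the T lineage, 158 changed with line, against 41, 0, 53, 17, 83 and 12 with DESeq2, line alone, the treatment field, no doublet removal, Xist-bearing cells only and without genes of other cell types, and 0 to 147 over the libraries left out. With diet 127 changed, against 24 with DESeq2, 2 with diet alone, 39 with the treatment field, 66 without genes of other cell types, and 28 to 133 over the libraries left out. Without T sub-cluster 1 the T lineage counts were 153 with line and 125 with diet. In neutrophils edgeR called 0 with line (330 at unadjusted p under 0.05, DESeq2 0), against 27 with no filter, 12 without doublet removal, 24 without genes of other cell types, and 0 to 70 over the libraries left out. With diet edgeR called 0 (743 at unadjusted p under 0.05), against 19 with DESeq2, 20 with RLE, 174 with no filter, 88 without doublet removal, 3 with Xist-bearing cells only, 210 without genes of other cell types, and 0 to 246 over the libraries left out.

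With an estimated correlation camera called 0 lists in each lineage, for line and for diet. With the preset one, the lists called with libraries left out ran from 5 to 9 for line in phagocytes (9 with all), 3 to 7 for line (3) and 5 to 10 for diet (10) in the T lineage, and 5 to 11 for diet in neutrophils (11). T lineage line calls were 6 with no filter, 6 without doublet removal, 6 with Xist-bearing cells only and 5 without genes of other cell types, and neutrophil diet calls were 3 with the treatment field. Directions turned for cytotoxicity with diet in the T lineage (camera adjusted p = 0.0484 without doublet removal), free erythrocyte RNA with diet in phagocytes (8.92e-51 to 0.0306 over the libraries left out, upward at 0.0306 without HFD_shYap) and cell cycle with line in neutrophils (8.26e-18 to 0.032, downward at 0.032 without LFD_shYap).

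Counting T and NK cells together moved the T share difference to 2.98 points for HFD_WT minus LFD_WT and 0.690 points for LFD_shYap minus LFD_WT. Thinning to 1000 UMIs, which merged both classes, moved the HFD_WT minus LFD_WT share to 2.39 points for T and NK cells and -7.21 points for phagocytes, and the LFD_shYap minus LFD_WT share to 0.119 and 0.632 points. Counting the low-depth cluster moved the phagocyte differences to -8.57 and -0.799 points. Without doublet removal the HFD_shYap minus HFD_WT share of neutrophils was -3.30 points. The same step turned list medians of free erythrocyte RNA in phagocytes (-1.29 for HFD_WT and -0.40 for LFD_shYap, both against LFD_WT), checkpoint ligands (0.10, HFD_shYap against HFD_WT) and cytotoxicity (-0.020, LFD_shYap against LFD_WT) in the T lineage. It turned log2 ratios of HFD_WT against LFD_WT to -0.79 for Ccl22, -0.10 for Il12b, -1.43 for Hbb-bt, -1.35 for Hba-a2, -1.59 for Hba-a1 and -1.32 for Hbb-bs in phagocytes and -2.63 for Gzmf, -3.09 for Gzmc and -0.10 for Prf1 in the T lineage. For LFD_shYap against LFD_WT it turned Hbb-bt (-0.31), Hba-a1 (-0.49), Hba-a2 (-0.48) and Hbb-bs (-0.63) in phagocytes, Gzmf (-2.47), Gzma (-0.67), Prf1 (-0.25), Vsir (0.20), Atf3 (0.018) and Trf (0.15) in the T lineage, and Top2a (-0.16) and Stmn1 (-0.066) in neutrophils. It also turned Oasl2 (0.18) for HFD_shYap against HFD_WT and Ifit2 (0.034) and Tnf (-0.57) for HFD_shYap against LFD_shYap in the T lineage, and Trf (-0.30) for the latter pair in neutrophils. TMM-scaled CPM turned Trf (-0.032, HFD_shYap against HFD_WT) and Uqcrq (-0.014, HFD_shYap against LFD_shYap) in phagocytes.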

Other observations

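Of the tests reported here, only the counts of T cell receptor alpha genes in Prss2-bearing cells were chosen after their result was seen; the gene lists used for NK and dendritic cells were also applied there after the data were seen, without a test.

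NK cells, which kill without prior sensitisation, had all 10 interferon response genes above the all-gene median in HFD_WT against LFD_WT (1.01, percentile 100), with Isg15 at 116 against 55.7 CPM, from 82 against 299 cells. Dissociation stress genes moved with them, with 11 of 12 members above the all-gene median (0.75, percentile 99.99). All 13 cell cycle genes were under it (-1.21, percentile 0), Gzmf was at 426 against 3563 CPM and the chemokine gene Ccl5 at 1588 against 495 CPM. In LFD_shYap against LFD_WT, NK cytotoxicity genes had a median of -0.89 (percentile 0), with Gzma at 1944 against 5188 CPM, and cell cycle genes of -1.53 (percentile 0). Dendritic cells of HFD_WT against LFD_WT had lower chemokines (-1.01, percentile 0) and interferon response genes (-0.62, percentile 0), with Ccl2 at 51.7 against 199 CPM and Ifit3 at 13.8 against 45.5 CPM. Macrophage markers there were at 4.97% against 9.27% of their phagocyte level, at which phagocyte RNA would give 20.3 against 120 CPM of Ccl2 and 1.72 against 5.73 CPM of Ifit3. Their hypoxia and glycolysis genes were higher (0.32, percentile 99.99), with Bnip3 at 39.1 against 19.6 CPM. In LFD_shYap against LFD_WT, all 11 interferon response genes of dendritic cells were under the all-gene median (-0.59, percentile 0), while macrophage markers there were at 4.87% against 9.27% of their phagocyte level.

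Fkbp5 and Zbtb16, which rose in phagocytes of the libraries labelled shYap, are known glucocorticoid targets, and a glucocorticoid response in all immune cells was put forward as a hypothesis. The other glucocorticoid target genes, 10 in number, had a median log2 fold change with line of 0.36 in phagocytes (percentile 100 of matched random lists), 0.24 in the T lineage (99.74) and 0.28 in neutrophils (96.32). The lowest percentile, 96.32, fell short of the bound set before the test, so the test left open whether the response may extend to all 3 lineages. Klf9 (1.14), Tsc22d3 (0.94) and Pik3ip1 (2.04) were among the phagocyte values.

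Prss2, whose gene ends 8122 bases from the first T cell receptor beta diversity segment, Trbd1, had 702 UMIs in the T lineage of HFD_WT against 2, 46 and 15 in LFD_WT, LFD_shYap and HFD_shYap. An expanded T cell clone was the hypothesis. Of the HFD_WT cells with at least 2 Prss2 UMIs, only 3 also held a Trbv UMI, with the most frequent Trbv gene in 33.3% of them, too few to decide. Trav10 was seen in 7 of the 10 such cells with a Trav UMI and in 0 of 124 other T lineage cells of HFD_WT, which a clone could give.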
